A study of Homo sapiens with 4 samples.

How the data were processed

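Total RNA from U937 cells with a hairpin against PIR and from U937 cells with the empty vector was extracted with TRIzol and cleaned on RNeasy columns, per the labels' protocols. Equal amounts from 3 extractions were mixed into 1 pool per condition, and each biotin-labelled target was hybridised to 2 HG-U133 Plus 2.0 arrays, per the series design text. Signals were produced with GCOS, per the submitters' processing notes; its version and further settings are not given in the sources used here.

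The deposited table holds 1 signal intensity per probe set and array on a linear scale. On each of the 4 arrays the mean intensity after trimming 2% of the probe sets at each end was 500.07, so the values are scaled to a common level; they are not centred and carry no direction. Median intensities were 62.5 and 68.5 on the knock-down arrays and 70.8 and 72.1 on the empty-vector arrays. Detection calls and scanner files were not used here, so no test of signal over background was made, and only the number of arrays and the brightness limit below bound the precision. Scaling to a common mean assumes that total signal is equal in the 2 pools.

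Of the 54675 probe sets, 62 AFFX controls were left out, except for the 3' and 5' probe sets of GAPDH and ACTB used to compare RNA integrity. Of the remaining 54613, 41091 had 1 gene symbol in the platform annotation, 1801 had several and were not named, and 11721 had none. The gene identifiers of 41037 named probe sets matched the reference gene table. Among probe sets without a symbol, 27 were higher and 38 lower by the rule below; they are not described further. Each of 19775 genes was represented by its probe set with the highest mean log2 value over the 4 arrays.

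Because the arrays of a condition share 1 RNA pool, they were averaged and treated as 1 sample, and no p-value was computed for the condition. Values were taken as log2(signal + 18), where 18 is the mean over arrays of the 25th percentile of signal, and fold changes are on this scale, which understates the change of dim genes. A gene met the size rule when the pools differed by at least 1 on the log2 scale (2-fold), all 4 array-by-array differences were at least 0.5 in that direction, and both arrays of the higher pool were at or above that array's 60th percentile of signal, called the brightness limit. A gene was counted as measured when both arrays of at least 1 pool reached that limit. The rule was also applied to the 2 splits of the arrays that mix the pools. For each of 31 gene lists, the median difference of the measured members was set against 10000 random lists of the same size, matched on mean log2 value in 20 bins; a list stood apart at or below the 2.5th or at or above the 97.5th percentile. This describes these 2 pools and is not a test of the condition.

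The rule for named genes took PIR, the 15 largest differences in each direction among genes that met the size rule and whose probe set identifier does not end in _x_at, up to 4 members per list that met the rule, and, for a list that stood apart with no such member, its 2 largest differences in the list's direction. This gave 75 genes. The size rule, the lists, the rule for named genes and the alternatives below were fixed before the data were examined. Genes named outside the rule are marked as chosen after their values were seen, or complete a count.

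On simulated arrays with the hybridisation error of these arrays, with 50 genes at each fold among 10288 measured genes, the size rule recovered 42% of genes changed 2-fold, 90% of those changed 3-fold, 88% of those changed 4-fold and none of those changed 1.5-fold, and called none of 10088 unchanged genes. The simulated errors were normal, and the splits of the real arrays that mix the pools called 11 and 10 genes, so the simulation understates false calls. Of 100 unshifted lists of 20 genes drawn at random, 3 stood apart, and all 20 lists shifted by 0.5 did. These simulated lists do not cover members that move together.

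Alternatives were no pseudocount and a pseudocount of 72, no brightness limit and the 75th percentile, quantile normalization and median scaling, a 1.5-fold limit, no margin over array pairs, the mean over all probe sets of a gene, each array left out in turn, and limma (lmFit and eBayes with trend) on the 4 arrays with and without the replica number as a block. The limma fits compare the 2 pools against hybridisation error and not the conditions. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, R 4.3.3 and limma 3.58.1 were used.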

Results

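U937 is a human myelomonocytic cell line derived from a histiocytic lymphoma. The series compared U937 cells that carried a lentiviral short hairpin against PIR with U937 cells that carried the empty pSICO-R vector. PIR encodes pirin, an iron-binding nuclear protein of the cupin family. Gene expression was measured on Affymetrix HG-U133 Plus 2.0 arrays, on which each probe set reports 1 transcript or a small group of transcripts. Each condition was represented by 1 RNA pool made from 3 extractions, and each pool was hybridised to 2 arrays, so 4 arrays were analysed. The 2 arrays of a pool repeat the hybridisation and not the culture. Errors given here are therefore SDs between 2 arrays of the same RNA (n = 2 arrays), the comparison is between 2 pools, and the design holds no replicate check of the condition and no p-value for it. The median SD between the 2 arrays was 0.07 on the log2 scale for the knock-down pool and 0.06 for the empty-vector pool over 10288 measured genes. Across these genes, which are not independent replicates, the Pearson correlation was 0.992 between the knock-down arrays, 0.993 between the empty-vector arrays, and 0.967 to 0.968 between arrays of different pools.

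PIR itself, the target of the hairpin, was lower in the knock-down pool. Its only probe set, 207469_s_at, had a signal of 87.5 ± 5.73 (SD, n = 2 arrays) in the knock-down pool and 1847 ± 48.6 in the empty-vector pool. This was a log2 difference of -4.15, or 17.7-fold, and the 4 array-by-array differences ran from -4.23 to -4.06. It was the largest difference among the genes that met the size rule. The knock-down signal lay below the brightness limit on both arrays, so the fold depends on the pseudocount: the log2 difference was -4.40 with none and -3.59 with a pseudocount 4 times larger.

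The first question was which transcripts differed between the 2 pools. Of the 10288 measured genes, 251 were at least 2-fold higher and 113 at least 2-fold lower in the knock-down pool, together 3.54% of measured genes. Of these, 12 were higher and 5 were lower by at least 4-fold. The same rule applied to the 2 splits of the arrays that put both pools on each side called 11 and 10 genes. Its margin over array pairs keeps genes called between the pools from being called in these splits. Without the margin the splits called 18 and 19 genes. At the level of probe sets, 502 were higher and 318 lower. In the dimmer pool, 75 of the 251 higher genes and 27 of the 113 lower genes lay below the brightness limit on both arrays, and the folds of these genes are the least certain. Leaving out 1 array gave 140 to 177 lower genes, the most without empty-vector replica 1.

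**Figure D1:**
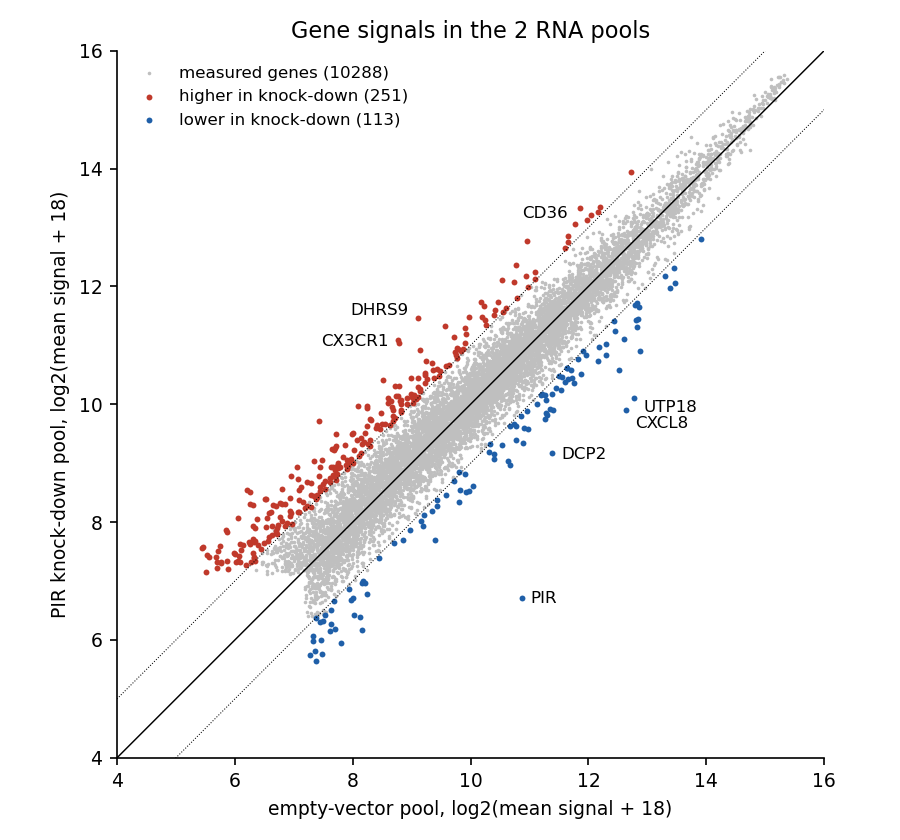
Each point is 1 of the 10288 measured genes, plotted by the log2 of its mean signal plus 18 in the empty-vector pool (horizontal axis) and in the PIR knock-down pool (vertical axis). Red points are the 251 genes that met the size rule as higher in knock-down and blue points the 113 lower ones, the solid line marks equal signals and the dotted lines 2-fold differences, and PIR lies farthest from the solid line.

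Among the 15 genes with the largest higher signals in the knock-down pool were DHRS9, FABP4, CX3CR1, CFP, FABP6 and BLNK, all more than 4-fold higher. DHRS9, a retinol dehydrogenase of the short-chain family, had a signal of 2802 ± 219 against 533.8 ± 6.43 in the empty-vector pool, a 5.10-fold difference, and its other 2 measured probe sets differed by 2.37 and 2.65 on the log2 scale. FABP4, a fatty acid carrier of adipocytes and macrophages, was 5.03-fold higher, and FABP6, an intestinal bile acid carrier, was 4.85-fold higher. CX3CR1, the fractalkine receptor of monocytes, was 4.97-fold higher (2154 ± 125 against 418.9 ± 14.6). CFP, which encodes the complement factor properdin, was 4.95-fold higher. BLNK, an adaptor of B cell receptor signalling, was 4.81-fold higher with signals of 2093 ± 33.0 and 421 ± 5.16. P2RY13, a purinergic receptor, DNAL4, a dynein light chain, and DPEP2, a membrane dipeptidase, were 4.77-fold, 4.45-fold and 4.41-fold higher. TRIM29, PDYN (the dynorphin precursor), CPB2, PYHIN1, KIF26B and RRAS completed the 15 highest, with folds from 3.81 for RRAS to 4.03 for TRIM29. In 10 of these 15 genes the empty-vector signal lay below the brightness limit on both arrays. KIF26B was the least certain, with array-by-array differences from 0.98 to 2.93.

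The 15 genes with the largest lower signals, PIR included, are given here without 3 genes whose probe set identifiers mark shared probes; 1 of these, CXCL8, was lower by more than any gene but PIR and is described with the NF-kB targets. UTP18, a factor of ribosomal RNA processing, had a signal of 1089 ± 8.63 against 7012 ± 166, a 6.35-fold difference, and its second probe set was lower by -2.19 on the log2 scale. DYNLT1, a dynein light chain, was 3.95-fold lower (1892 ± 5.66 against 7536 ± 142). DCP2, the mRNA decapping enzyme, was 4.63-fold lower on its brightest probe set (561.3 ± 18.7 against 2664 ± 1.06), but its other measured probe sets disagreed, with log2 differences of -0.80 and 0.57. WSB2 was 3.23-fold lower, IL1RAP, the accessory chain of the interleukin-1 receptor, 3.33-fold lower, although the second measured IL1RAP probe set differed by only -0.51. The DDX5 probe set 225886_at was 3.02-fold lower; another probe set annotated to DDX5 and to microRNA genes was not assigned to a gene. PTPRG, a receptor tyrosine phosphatase, was 3.33-fold lower from an empty-vector signal of 259.8, and its second measured probe set gave -1.69. The remaining 7 also had low signals: CLDN19, C2CD4C, HNRNPA3P1, CARMIL3, SYT15, CIB3 and CD1C, with empty-vector signals from 147.8 for C2CD4C to 285.4 for SYT15. HNRNPA3P1, SYT15 and CD1C had array-by-array differences as small as -0.56, -0.59 and -0.58.

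Monocyte and macrophage genes were higher as a group. Of 27 measured members, 22 had a positive difference, 5 met the size rule as higher and none as lower, and the median log2 difference was 0.58, above all of the 10000 random lists matched on brightness. Without the brightness limit the median was 0.36, at the 100th percentile. CX3CR1 led the list. ITGAM, the CD11b integrin chain, was 3.74-fold higher (1350.0 ± 141 against 347.2 ± 33.0). CD36, a scavenger receptor, was 2.43-fold higher (8496 ± 667 against 3483 ± 99.4), and its other measured probe sets were 3.62-fold and 3.70-fold higher. CTSS, a lysosomal cysteine protease, was 2.26-fold higher, with its other measured probe sets both at 0.78 on the log2 scale. LILRB2, an inhibitory leukocyte receptor with a log2 difference of 1.12, was the fifth. Members chosen after their values were seen went the other way: S100A8 and S100A9, the calprotectin subunits, had differences of -0.78 and -0.77, and neither met the size rule. LYZ, the lysozyme gene, differed by 0.01.

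Adhesion and integrin genes also stood above all of the random lists, with a median of 0.43 over 26 members, of which 5 met the rule as higher and none as lower. This list shares 6 of its genes with other lists. Besides ITGAM, the members named by the rule were ITGB5 (2.32-fold), ICAM2 (2.29-fold) and ITGA5 (2.21-fold, 8884 ± 331 against 4003 ± 4.10), and ITGAV, at 1.09 on the log2 scale, was the fifth. The second measured ITGB5 probe set differed by only 0.22 and that of ICAM2 by 0.90. The identifier of the ITGB5 probe set at 2.32-fold marks probes shared with related transcripts. Granule genes of neutrophils did not stand apart, with a median of 0.19 at the 95.4th percentile, and 0.04 after quantile normalization. CEACAM6, an adhesion molecule of granulocytes, was 2.94-fold higher (3380 ± 55.1 against 1140 ± 70.9), and 3.89-fold higher on its other probe set. SERPINB1, an inhibitor of neutrophil elastase, was 2.84-fold lower (2178 ± 30.6 against 6220 ± 179), with 2 further probe sets lower and a dim one at 0.16. Among 6 measured subunits of the NADPH oxidase, CYBB alone met the rule, at 2.00-fold higher, and its other measured probe set, at 0.87 on the log2 scale, did not. The myeloid transcription factors had a median of 0.07, at the 67.2nd percentile, and of 0.0005, at the 32.2nd, without knock-down replica 1. In that list FOS was 2.14-fold higher and ID1 2.10-fold lower, and the other 20 measured members met the rule in neither direction. The homeobox and progenitor list had only 2 measured members, PBX3 at 0.12 and MEIS1 at 0.13.

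Cell cycle genes were lower as a group. All 28 measured mitotic genes had a negative difference, with a median of -0.62 (1.53-fold), below all of the random lists, although only 2 reached the 2-fold limit. These were MKI67, the proliferation antigen Ki-67, at 2.42-fold lower (2056 ± 167 against 5001 ± 49.1) and PLK1, a mitotic kinase, at 2.32-fold lower (1368 ± 103 against 3188 ± 30.3). The 3 other MKI67 probe sets had log2 differences of -0.94, -1.14 and -1.10. Genes of DNA replication were lower by a median of -0.31 (1.24-fold), also below all of the random lists, and 21 of 24 were negative. None of them met the size rule on its brightest probe set. The members with the largest differences were MCM2, a subunit of the replicative helicase, at -0.72 and RRM2, a ribonucleotide reductase subunit, at -0.70. The other RRM2 probe set gave -1.44 and met the size rule as lower. Targets of p53 and senescence markers did not stand apart (median 0.11, 74.2nd percentile; 0.03 without empty-vector replica 1 and 0.04 without knock-down replica 2). RRM2B, the p53-inducible ribonucleotide reductase subunit, was 2.67-fold lower and was the only member to meet the rule. CDKN1A, the p21 gene, named here after its value was seen, differed by 0.11.

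Genes of cholesterol synthesis were higher in the knock-down pool. Of 19 measured members, 18 had a positive difference and 6 met the size rule as higher, with a median of 0.58 (1.49-fold) above all of the random lists. MSMO1, an oxidase that removes sterol methyl groups, was 2.99-fold higher (4397 ± 261 against 1458 ± 52.3), and DHCR7, a late reductase of the pathway, was 2.85-fold higher (2848 ± 167 against 988.5 ± 20.01) with a second probe set at 1.32 on the log2 scale. TM7SF2, a sterol reductase, and MVD, a mevalonate pathway decarboxylase, were 2.48-fold and 2.28-fold higher from empty-vector signals of 48.8 and 86.6, below the brightness limit. HSD17B7 was the negative member, at -0.81. Genes of fatty acid synthesis and uptake had a median of 0.55 (1.46-fold), again above all of the random lists, with 4 of 14 higher. These were FABP4, CD36, FADS2, a fatty acid desaturase (2.11-fold), and PPARG, the nuclear receptor of adipocyte and macrophage lipid handling (2.75-fold, 1373 ± 85.8 against 488.5 ± 56.9). The median of this list was 0.22, at the 97.2nd percentile, when all probe sets of a gene were averaged. It was 0.31, at the 99.8th percentile, without the brightness limit. FASN, the fatty acid synthase, named after its value was seen, differed by 0.13.

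**Figure D2:**
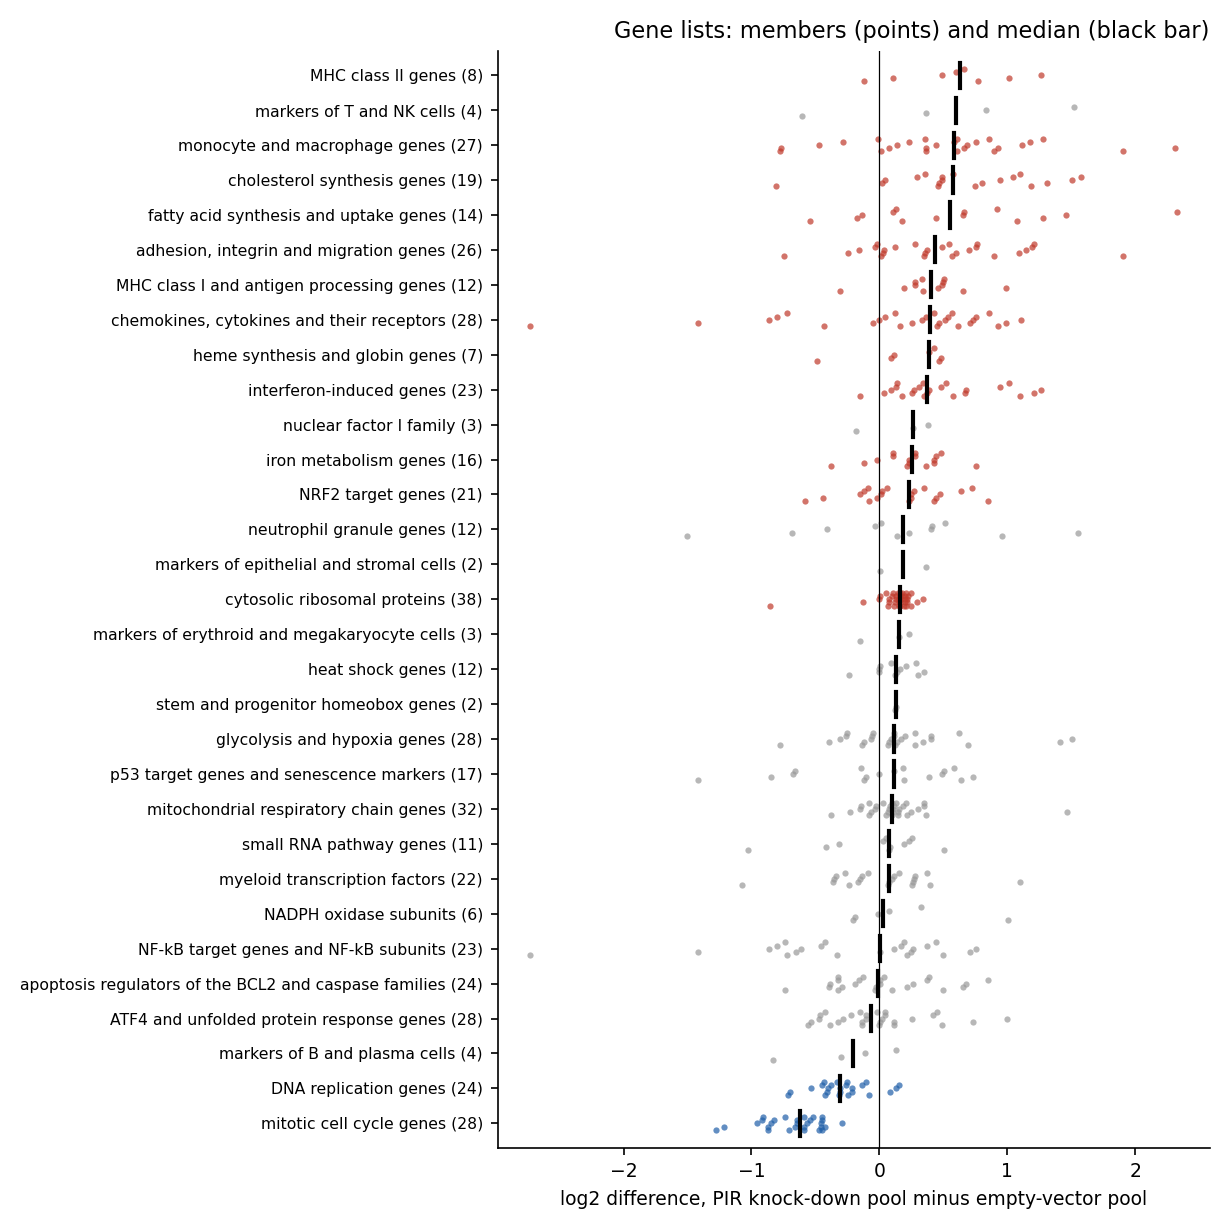
Points are the measured members of each gene list, placed by the log2 difference between the PIR knock-down pool and the empty-vector pool (horizontal axis), and black bars are the list medians; the number of members is in brackets. Red lists stood above the range of matched random lists, blue lists below it, and grey lists within it, and the mitotic and DNA replication lists have the lowest medians, at -0.62 and -0.31.

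Genes of antigen presentation and interferon-induced genes were higher. In the MHC class II list, 2 of 8 measured members met the rule, HLA-DPA1 at 2.40-fold (530 ± 17.9 against 210.7 ± 4.60) and HLA-DRB1 at 2.02-fold, and the median was 0.63 (1.55-fold, 99.9th percentile). The identifier of the HLA-DRB1 probe set marks probes shared with related transcripts, so its signal is not specific to that gene. The MHC class I and antigen processing list had a median of 0.40 (1.32-fold), above all of the random lists, with 11 of 12 members positive and none at the 2-fold limit. PSMB9, an immunoproteasome subunit, and ERAP1, a peptide trimming enzyme, had its largest differences, 0.99 and 0.66. Of the interferon-induced genes, 22 of 23 had a positive difference and 4 met the rule, with a median of 0.38 (1.30-fold, 99.8th percentile). These were IFIH1, an RNA sensor (2.40-fold, 1058 ± 1.41 against 431.6 ± 40.9, with a second measured probe set at 0.51), SAMD9 (2.31-fold, second probe set 0.90), OAS2 (2.14-fold, from an empty-vector signal of 54.95) and IRF9 (2.02-fold). ISG15, named after its value was seen, differed by 0.13.

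NF-kB targets and subunits had differences of both signs and did not stand apart as a list, with a median of 0.01 at the 33.7th percentile. The sign of this median was not stable: it was -0.09 (5.37th percentile) without empty-vector replica 1 and 0.18 (91.4th) under the 75th percentile limit on brightness. Pirin is known to bind BCL3, a partner of NF-kB. Of 23 measured members, 2 met the size rule, both lower. CXCL8, the interleukin-8 gene, was 6.65-fold lower (940.1 ± 30.9 against 6354 ± 396), and its second probe set gave a log2 difference of -2.90. CCL2, a monocyte chemoattractant, was 2.67-fold lower (3986 ± 57.8 against 10668 ± 488). Further members, named after their values were seen, did not meet the rule: CXCL2 had -0.86, TNF -0.80 and IL1B -0.72, but ICAM1 had 0.75, CCL5 0.71, BCL2A1 0.49 and TNFAIP3 0.37, so the targets themselves went both ways. The subunits NFKB1, NFKB2, RELA, RELB and REL, also named after their values were seen, had 0.26, 0.11, 0.17, 0.22 and 0.44. The list of chemokines, cytokines and receptors had a median of 0.40, above all of the random lists, although CXCL8 and CCL2 belong to it. IL18, a cytokine of the interleukin-1 family, was its only member that met the rule as higher, at 2.15-fold (1120 ± 6.86 against 510.5 ± 31.0). Without the brightness limit the median of this list was 0.11, at the 93.7th percentile. It shares 15 of its genes with other lists.

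**Figure D3:**
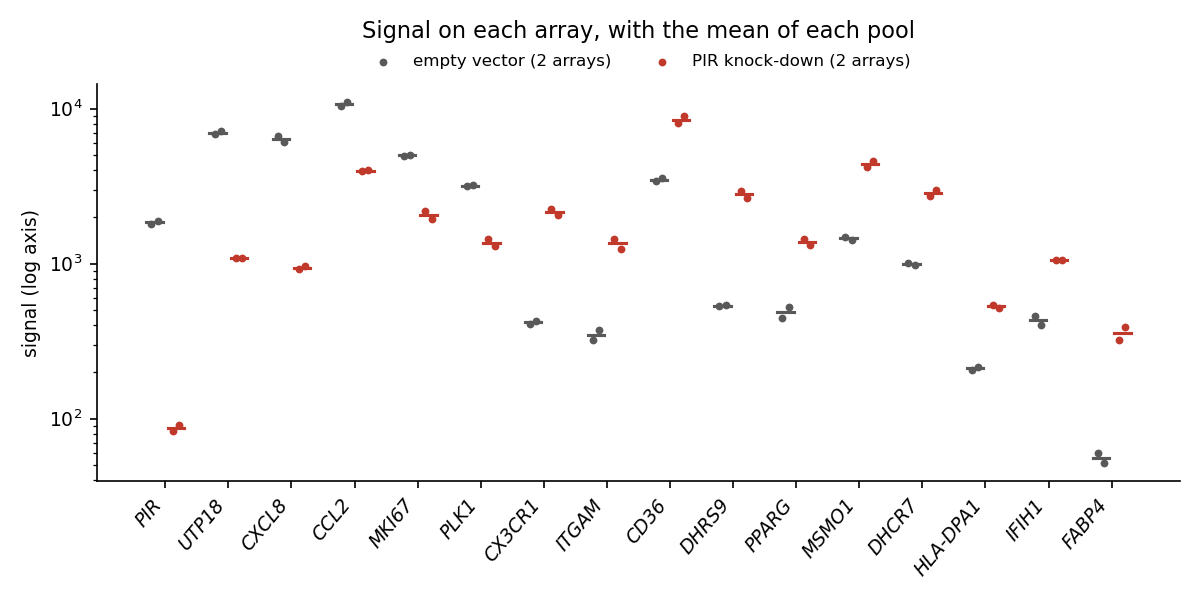
Points are signals on single arrays (logarithmic vertical axis) for 16 of the genes named in the text, grey for the 2 empty-vector arrays and red for the 2 PIR knock-down arrays, and short lines are the mean of each pool. All genes shown met the size rule, which requires both arrays of the higher pool to lie above both arrays of the other. An example is CX3CR1, with means of 2154 and 418.9.

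NRF2 targets had a median of 0.24 (1.18-fold, 98.9th percentile), with none of 21 members at the 2-fold limit on its brightest probe set. The percentile was 65.3 after quantile normalization and 31.6 under the stricter brightness limit, and it was 85.7 without knock-down replica 2, 96.3 without knock-down replica 1 and 96.9 without empty-vector replica 1, so this list did not hold its place. ABCC2, a transporter, and AKR1C1, an aldo-keto reductase of a closely related gene family, had the largest positive differences, 0.85 and 0.73, at signals of 170.5 and 165 in the knock-down pool. The other measured AKR1C1 probe set was 2.09-fold higher and met the size rule; the identifiers of both mark probes shared with related transcripts. NQO1, named after its value was seen, had -0.44. Iron metabolism genes had a median of 0.26 (98.6th percentile), led by SLC40A1, the iron exporter ferroportin, at 0.76 (690.8 ± 24.8 against 401 ± 9.40), and the 7 measured heme synthesis genes had a median of 0.39 (98.96th percentile), led by FECH at 0.49 and UROS at 0.46. Other measured probe sets gave 0.65 and 0.10 for FECH and 0.22 and -0.15 for UROS, and ALAS1 and FECH are also in the iron list. None of the 16 or of the 7 met the size rule. With single arrays left out, the iron list fell to the 96.6th percentile without knock-down replica 1 and to the 96.3rd without empty-vector replica 2, and the heme list to the 96.95th without knock-down replica 1 and the 96.7th without empty-vector replica 1. Cytosolic ribosomal protein genes had a median of 0.16 (99.5th percentile) in the authors' scaling and -0.01 after quantile normalization, and 0.07 (85.5th percentile) with all probe sets averaged, so the direction reversed under the former; RPL27 and RPS4X had the largest differences, 0.34 and 0.30.

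Of the 31 lists, 12 stood above and 2 below the range of matched random lists. About 5% would fall outside it if genes varied independently, but members of a list can move together and some lists share genes. The 5% is therefore no measure of what separate cultures of the same condition would give. The lists of glycolysis and hypoxia (85.9th percentile), the respiratory chain (87.1st), heat shock genes (82.2nd), the unfolded protein response (13.1st), BCL2 family and caspase genes (22.3rd), small RNA pathway genes (63.6th) and the nuclear factor I family (80.7th) stayed within it, but their places were not stable: without knock-down replica 2 the unfolded protein response list was at the 37.6th percentile, the BCL2 family list at the 5.51st and the nuclear factor I list at the 63.5th, and with all probe sets averaged the heat shock list was at the 50.7th and the small RNA list at the 33.6th. Single members of these lists met the rule. PFKFB4, a regulator of glycolysis, and ALDOC, the aldolase of brain, were 2.84-fold and 2.66-fold higher. PPARGC1A, a coactivator of mitochondrial genes, was 2.77-fold higher (846 ± 43.6 against 294 ± 24.6), and DICER1, the RNase that processes microRNA and hairpin precursors, was 2.03-fold lower (1403 ± 27.3 against 2872 ± 84.2), where its other measured probe sets gave -0.49 and -1.297 on the log2 scale. Few markers of other cell types were measured: 4 of T and NK cells (median 0.60, 97.4th percentile), 4 of B and plasma cells (-0.21, 10.9th), 3 of erythroid and megakaryocyte cells (0.15, 64.7th) and 2 of epithelial and stromal cells (0.19, 65.95th). The T and NK cell list lay at the 98.4th percentile without knock-down replica 1, the 98.8th without empty-vector replica 1 and the 99.3rd without empty-vector replica 2, and the B cell list at the 1.42nd without empty-vector replica 1, but its median turned to 0.39 (85.5th percentile) with all probe sets averaged. The median of the epithelial and stromal list changed sign, to -0.58 (7.83rd percentile) without empty-vector replica 1 and -0.18 without empty-vector replica 2, and that of the erythroid list fell to 0.03 without empty-vector replica 2. IL7R, the interleukin-7 receptor of lymphocytes, was 2.88-fold higher at a signal of 252.1 ± 27.6. The ratio of 3' to 5' control probe sets, a measure of RNA integrity, differed between the pools by 0.0023 on the log2 scale for GAPDH and -0.0024 for ACTB.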

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

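PIR was lower under every alternative run, with a log2 difference of -4.40 without a pseudocount, -3.59 with the larger one, and -4.20 to -4.09 with 1 array left out. The count of higher genes, 251, became 164 with the larger pseudocount, 142 with the 75th percentile limit, 155 with the mean over probe sets, 718 at 1.5-fold and 448 without the brightness limit. The count of lower genes, 113, became 68 with the mean over probe sets, 391 at 1.5-fold and 414 without the limit. A stricter limit or lower fold changes counts by construction, and 138 of the 155 and 58 of the 68 were among the main calls; the cause of the other changes was not tested. Without the brightness limit the mixed splits called up to 383 genes against 11, so those counts carry much hybridisation error; without the margin over array pairs they called up to 19. Leaving out 1 array gave 275 to 304 higher and 140 to 177 lower genes, each above the main count. With 1 array out the rule averages fewer arrays and checks fewer array pairs, so it is noisier and looser by construction. The value 177 came without empty-vector replica 1, and 101 of the 113 lower genes were among it. The limma test against hybridisation error, with Benjamini-Hochberg adjusted p under 0.05 and a 2-fold limit, gave 254 and 117 genes, and 255 and 119 with the replicate block. Without the 2-fold limit these fits gave 4201 and 4119 of 10288 genes, so the limit shared with the size rule largely set the counts. The replica numbers do not pair the samples by design, and the deviations of same-numbered arrays had a correlation of -0.0045. Between 10 and 14 lists stood apart under the alternatives, against 14. The ribosomal protein list reversed to -0.0105 after quantile normalization, and the NRF2, fatty acid, iron, heme, cytokine and ribosomal lists fell inside the random range under at least 1 alternative; the T and NK cell list moved outside it under 6 alternatives and the B cell list under 1. The monocyte, adhesion, cholesterol, MHC, interferon, mitotic and DNA replication lists stood apart under all those run. Under the 75th percentile limit the B cell and epithelial lists, and with the mean over probe sets the epithelial list, had no measured member and gave no value. The median difference of measured genes was 0.05, 0.02 after quantile normalization and -0.01 after median scaling. The table carries no background estimate, so the folds of dim genes rest on the pseudocount and the brightness limit.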

Other observations

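The lysosomal and cilium lists, and the tests of scaling and of culture growth, were chosen only after the results were seen. Genes of the lysosome were higher in the knock-down pool. Of 50 measured genes for lysosomal enzymes and membrane proteins, 46 had a positive difference, 10 met the size rule as higher and none as lower, and the median was 0.45 (1.37-fold), above all of 10000 matched random lists and 0.48 after quantile normalization. These 10 include CTSS, which is also in the monocyte and macrophage list. CTSO and CTSA, lysosomal peptidases, were 2.57-fold and 2.26-fold higher, GM2A, a ganglioside activator protein, 2.36-fold, DNASE2, an acid nuclease, 2.29-fold, NPC1, a cholesterol exporter, 2.22-fold, and SMPD1, acid sphingomyelinase, 2.10-fold. ARSB and IDS, a pair of sulfatases, went the other way by 1.84-fold and 1.68-fold without meeting the rule. The probe set identifiers of ARSB, IDS and DNASE2 mark probes shared with related transcripts. The empty-vector signal of CTSO was 179.85 ± 72.1, so its fold is uncertain. Genes of intraflagellar transport and the ciliary base had a smaller median of 0.25 (1.19-fold, 99.4th percentile), with 47 of 53 positive and 5 higher. After quantile normalization the median was 0.20, at the 98.7th percentile. The 5 were DYNC2LI1 (2.83-fold), WDR19 (2.24-fold), TCTN1 (2.23-fold), BBS9 (2.10-fold) and IFT70B (2.02-fold). The empty-vector signal of TCTN1, 86.2, lay below the brightness limit. These genes were picked up from the called genes themselves, so their lists are not independent evidence.

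The first pattern is the 364 genes that met the size rule, against technical sources. The splits that mix the pools gave at most 11 genes, but the margin over array pairs keeps the 364 genes themselves from being called there. Without that margin the mixed splits gave at most 19 genes, against 257 higher and 123 lower between the pools. This argues against hybridisation noise as the main source. Among 238 other measured probe sets of 156 of these genes, 81.9% differed the same way by at least 0.5. Of all second probe sets, 12.03% lay that far in the commoner direction. This argues against single faulty probe sets as the main source among these 156 genes. The rest of the 364 genes had no other measured probe set and were not checked. Some probe sets disagreed, such as those of DCP2. With all probe sets of a gene averaged, 138 of the 251 higher and 58 of the 113 lower genes still met the rule. The 3' to 5' ratio of control probe sets differed by at most 0.0024 in size between the pools, which argues against a difference in RNA integrity. Variation between cultures stays open, since each condition has 1 pool. Labelling differences that the 3' to 5' ratio does not reach also stay open, since each pool gave 1 labelled target.

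Differences between the 2 cell populations other than loss of PIR were weighed for the same genes. The most extreme median of 100 neighbouring measured genes was -0.13, and the highest of 100 random gene orders was 0.20, which argues against copy number changes over stretches of that length. An interferon response to the hairpin may contribute: its gene list lay at percentile 99.82, with 22 of 23 measured members positive. Of these 23, 4 met the size rule as higher, against 251 of all 10288 measured genes. ISG15 differed by 0.13, and how many of the other higher genes such a response could reach was not tested. Of the lower genes, 84 were well expressed in the empty-vector pool, PIR itself included. Silencing of other transcripts by the single hairpin could account for some of the others, such as UTP18 and DYNLT1. This cannot be told apart from an effect of PIR loss, because transcript sequences were not searched here for the hairpin's seed and there is 1 hairpin.

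The third pattern is that cell cycle genes were lower while monocyte and macrophage genes were higher. Scaling or compression of bright signals is argued against, since the mitotic median stayed at -0.61 under the scaling that brought it nearest to 0 and all 3 lists stayed outside the range of brightness-matched lists. An effect of the knock-down itself stays open and untested. In the monocyte and macrophage list, 22 of 27 measured members were positive. Members chosen after their values were seen did not move with that list: S100A8 (-0.78), S100A9 (-0.77) and LYZ (0.01). Nor did the myeloid transcription factor list (median 0.07, 67.2nd percentile, and 0.0005 without knock-down replica 1). These values do not decide whether loss of PIR was the cause. A difference in culture growth at harvest unrelated to the hairpin could give the same mitotic median of -0.62 and cannot be told apart with 1 pool per condition.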
